A study of Mus musculus with 4 samples.

How the data were processed

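Bulk RNA-seq by SMART-Seq2, a full-length cDNA method that amplifies RNA from few cells by PCR, was measured in 4 libraries of mouse stomach corpus cells. Per the labels' protocols, gastric units were released by chelation, digested to single cells and sorted by flow cytometry as living cells carrying the epithelial surface protein EpCAM. The mice carried a reporter in which the red fluorescent protein tdTomato is made from the Iqgap3 locus, and the sort split the cells into a reporter-high fraction (IQ3pos) and a low or negative one (IQ3neg). Each fraction has 1 library pooled from 3 mice (IQ3pos_1909A and IQ3neg_1909B) and 1 pooled from 4 mice (IQ3pos_1910A and IQ3neg_1910B).

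The deposited table gives CPM, counts per 1000000 reads assigned to genes, for each gene symbol and library. Reads were handled with STAR 2.7.1a, featureCounts of Subread 2.0.0 and edgeR on GRCm38/mm10, per the submitters' processing notes, which give no role or order for them. The gene annotation, the strand setting and the treatment of multi-mapped or duplicate reads are not given in the sources used here. Each deposited CPM column sums to 1000000, so no factor for library composition had been applied. Every value was a multiple of a single step per library: 100% of the values above 0 came out within 0.05 of a whole read. Whole reads were recovered in this way, with totals of 90714929, 115016307, 279125309 and 418401262 in IQ3pos_1909A, IQ3neg_1909B, IQ3pos_1910A and IQ3neg_1910B. A single read was worth 0.0110, 0.00869, 0.00358 and 0.00239 CPM in the same order. SMART-Seq2 reads carry no molecular identifiers, so intervals based on reads cover counting error only and leave out the loss of transcripts before amplification.

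The design fixed before the data were examined foresaw edgeR on counts, with limma on log2(value + 1) should the unit be normalized. As the unit was CPM, the main test was limma-trend (limma 3.58.1, R 4.3.3) on log2(CPM + 1) for the 13019 genes with a mean of at least 1 CPM, IQ3pos minus IQ3neg, with no block, two-sided, and Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(CPM + 1) scale, which understates the change of genes of low level, and their SE is limma's moderated one. With 2 libraries per group, 2 residual degrees of freedom were joined by 3.61 prior ones. The p-values measure the spread between libraries of pooled mice, part of which may be technical. As the CPM carry no composition factor, list medians are also given relative to the median of all tested genes, and TMM-scaled values were computed as an alternative added after seeing the data.

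Of 55335 rows, 53647 (96.9%) match a symbol of the GENCODE reference for the same genome build. A further 109 rows repeat a symbol and were kept apart, and 27 carry a date in place of a symbol and were not named. Coordinates are from GENCODE vM21 on GRCm38, 1-based. Try4 and Try10, Akr1c14 and Akr1c19, Hba-a1 and Hba-a2, and the histone genes belong to families of near-identical copies, and reads may have been split among them.

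Named genes followed a rule fixed beforehand. It takes Iqgap3, Iqgap1 and Iqgap2; in each direction the 10 genes of largest change past the threshold with a mean log2(CPM + 1) of at least 5 and both libraries of one group above both of the other, filled by unadjusted p where fewer pass, leaving out ribosomal protein genes and unnamed models; and from each list the members past the threshold, or the 2 of highest mean CPM where none passes. Any other list member named was chosen after its value was seen. A gene that the rule takes is not reported here.

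The 32 gene lists were fixed before the data were examined, and 29 had at least 3 tested members. Each was tested with camera (preset correlation 0.01) on the limma fit, adjusted over the 29 lists, with camera at an estimated correlation and fry beside it. No list passed at an estimated correlation. There camera rests on the 2 residual degrees of freedom, so few lists could pass at any correlation. The cytosolic ribosomal proteins, with an estimated correlation of 0.0193, went from a camera p of 1.82e-24 to 0.0133. Failure at an estimated correlation is therefore weak evidence against a list. The estimate did exceed the preset for other lists, such as 0.630 for G2 and mitosis. Fry, which asks whether a set's genes move one way without comparing them with other genes, passed the cytosolic ribosomal proteins (adjusted p = 0.0146). Counts "adjusted over the list alone" use Benjamini-Hochberg within a list. No gene of any list passed over all genes tested in the main test.

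Alternatives were other pseudocounts, filters and scalings, each library left out in turn, a block for the library number, and count tests on the recovered reads with edgeR 4.0.16 and DESeq2 1.42.0. The edgeR quasi-likelihood test (TMM, filterByExpr, legacy=FALSE) called 11 genes higher and 38 lower of 16831. The older form of that test, the likelihood ratio test, a test against a 2-fold change, limma-voom and the DESeq2 Wald test were also run.

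The procedures were tested on simulated data with the real libraries' depths and dispersions for IQ3pos against IQ3neg. Among 11756 genes, limma recovered 7.61% of genes changed 4-fold and 37.0% of those changed 16-fold, and 10 of its 51 calls were false. Among 12871 genes, edgeR recovered 2.02% and 32.7%, and 6 of its 40 calls were false. The reporter transcript itself was not analysed here.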

Results

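RNA-seq profiles were compared between 2 sorted fractions of epithelial cells from the stomach corpus of C57BL/6 mice aged 6 to 8 weeks. IQ3pos cells were bright for a tdTomato reporter of Iqgap3, a scaffold protein of the IQGAP family, and IQ3neg cells were dim or dark for it. The series asks which genes mark corpus cells that express Iqgap3, in a study of stem cell proliferation. Each fraction had 2 libraries, 1 from a pool of 3 mice (IQ3pos_1909A and IQ3neg_1909B) and 1 from a pool of 4 mice (IQ3pos_1910A and IQ3neg_1910B). Depth was high, from 90714929 to 418401262 reads in genes per library, so counting error was small for all but the lowest genes.

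A handful of secretory transcripts took up much of the IQ3neg libraries. Clps, which encodes the lipase cofactor colipase, made up 34.1% and 27.7% of reads in IQ3neg_1909B and IQ3neg_1910B, against 3.17% and 0.714% in IQ3pos_1909A and IQ3pos_1910A. Together with Pla2g1b (a secreted phospholipase), Pgc (pepsinogen C) and Chia1 (acidic chitinase), it held 50.8% and 48.9% of IQ3neg reads and 6.00% and 2.11% of IQ3pos reads. Since CPM are shares of a library, the remaining genes read lower in IQ3neg: the median gene was 0.68 higher in IQ3pos on the log2 scale, 1.60-fold, and 0.04 higher after TMM scaling. Medians of gene groups are therefore given relative to this median. Counts adjusted over a list alone test CPM against no change and still carry the shift, so for most lists they are also given under 4 settings that take it out, chosen after seeing the data, in this order: TMM-scaled CPM, DESeq2-scaled CPM, CPM without the 20 most abundant genes and edgeR with TMM.

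**Figure D1:**
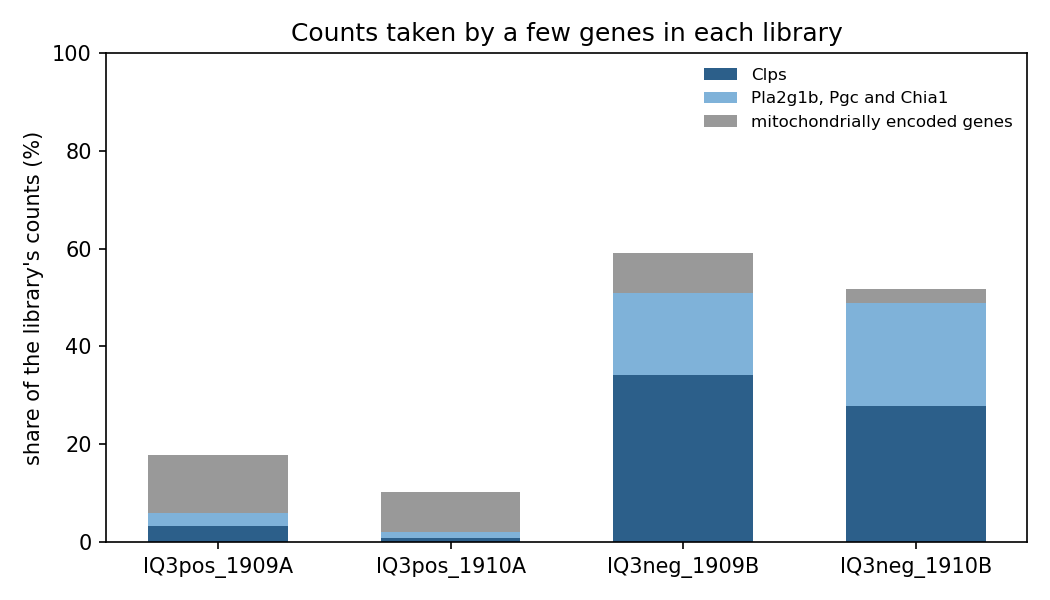
Share of each library's counts (y axis, percent) taken by Clps, by Pla2g1b, Pgc and Chia1 together, and by the mitochondrially encoded genes, in the 4 libraries (x axis). Clps alone took 34.1% and 27.7% of the IQ3neg libraries and 3.17% and 0.714% of the IQ3pos libraries.

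The first principal component of log2(CPM + 1), with 52.0% of the variance, set both IQ3pos libraries apart from both IQ3neg libraries. Across genes, r was 0.767 between the IQ3pos libraries and 0.826 between the IQ3neg libraries, and from 0.663 to 0.776 between fractions; genes are not independent replicates. IQ3pos_1910A correlated with IQ3neg_1910B (0.776) about as well as with IQ3pos_1909A. Among the 13019 tested genes, with TMM-scaled CPM, 3210 (24.7%) were higher in both IQ3pos libraries than in both IQ3neg libraries and 2995 (23.0%) were lower in both, where chance order gives 16.7% each. On CPM, which carry the shift, these counts were 5319 and 1843.

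No single gene passed limma's test at an adjusted p of 0.05, in either direction (0 higher, 0 lower, smallest adjusted p = 0.0542). At an unadjusted p under 0.05, 2373 genes were higher and 648 lower in IQ3pos, so 78.6% of these were higher; with TMM-scaled CPM the share was 47.9%. Calls depended on the tool and the scaling. Limma on TMM-scaled CPM called 6 genes higher and 24 lower, edgeR on the recovered reads 11 and 38, and the DESeq2 Wald test 427 and 1705.

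Of the 10 leading higher genes, Gkn1, Gkn2 and Tff1 are on the pit cell list, Tff2 on the mucous neck list, Atp4b on the parietal list and Smc2 on the list of G2 and mitosis. Gkn1, a gastrokine of surface mucous cells, stood at 5144 ± 281 CPM in IQ3pos and 648 ± 69.0 in IQ3neg (SD, n = 2 each), a log2 difference of 2.99 (SE 0.24, limma adjusted p = 0.0542). Its neighbour Gkn2 stood at 3381 ± 254 against 408 ± 125 CPM. Both lie on chromosome 6 of GRCm38, Gkn1 at 87345650 to 87350942 and Gkn2 at 87373357 to 87379497. The trefoil factor genes Tff1 and Tff2, on chromosome 17, differed by 3.12 and 3.28, and Lgals2, a galectin, by 3.43. Atp4b, the beta subunit of the acid-secreting proton pump, differed by 3.09. The rule also named Akr1c14 (3.19), Akr1c19 (2.65), Galntl6 (2.99) and the condensin gene Smc2 (4.63). With TMM-scaled CPM, Gkn1, Gkn2, Tff1, Tff2, Lgals2 and Akr1c14 passed limma's threshold.

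Of the 10 genes that led in the other direction, 6 are on the enteroendocrine list. Chga, encoding the granule protein chromogranin A, stood at 58.1 ± 19.9 CPM in IQ3pos and 2253 ± 144 in IQ3neg, a log2 difference of −5.29 (SE 0.33, limma adjusted p = 0.0542). Sst, encoding somatostatin, stood at 93.1 ± 40.2 against 6737 ± 2938 CPM, and Hdc, the histamine-forming enzyme of enterochromaffin-like cells, at 16.7 ± 3.70 against 518 ± 109. Chgb, Scg5, Resp18 and Slc18a2, which serve secretory granules and monoamine storage, differed by −5.16, −4.13, −5.48 and −3.05. The cytoskeletal gene Map1b differed by −5.15, and the trypsinogen genes Try4 and Try10 by −4.47 and −4.13. With TMM-scaled CPM these 10 genes passed limma's threshold.

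Iqgap3, on chromosome 3 at 88081971 to 88121048, was the gene behind the sort, so its own level checks the fractions and is no finding. It was low throughout, at 0.220 and 9.32 CPM in IQ3pos_1909A and IQ3pos_1910A and 0.0435 and 0.452 CPM in IQ3neg_1909B and IQ3neg_1910B. These values rest on 20, 2602, 5 and 189 reads, and the first 2 have 95% exact Poisson intervals of 0.135 to 0.340 and 8.97 to 9.69 CPM. IQ3pos held more among the 3-mouse pools, 5.07-fold, and among the 4-mouse pools, 20.6-fold, but IQ3pos_1909A lay below IQ3neg_1910B, and the log2 difference of 1.53 (SE 1.24) did not pass (limma adjusted p = 0.493). Without IQ3pos_1910A the fitted difference was −0.01, and it reached 4.02 in edgeR with library size only. Iqgap2 stood at 97.6 ± 41.7 CPM in IQ3pos and 15.7 ± 5.93 in IQ3neg, and Iqgap1 at 536 ± 200 and 300.1 ± 61.7. Of the 3 family members, Iqgap2 rose when adjusted over the list alone, a call that held without IQ3pos_1909A and was lost without any one of the other libraries, without the 20 most abundant genes and in edgeR with TMM, and the list did not pass camera (adjusted p = 0.191).

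**Figure D2:**
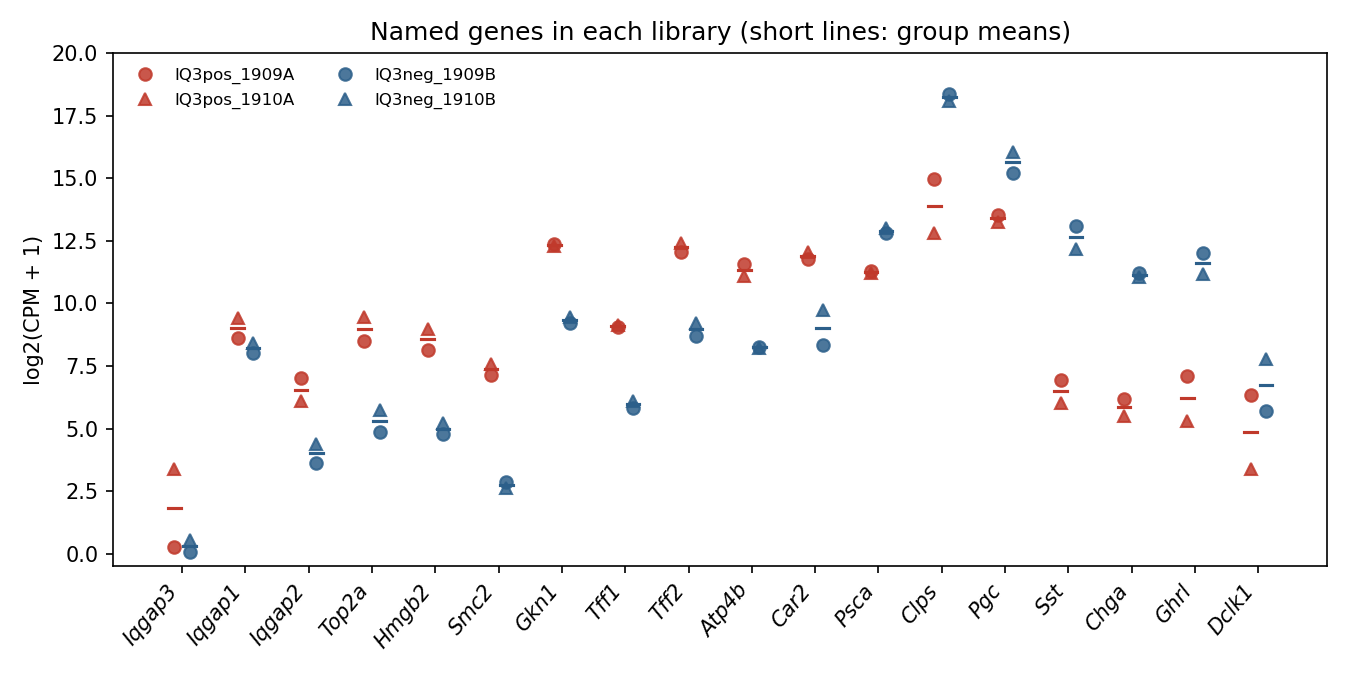
log2(CPM + 1) (y axis) of 18 named genes (x axis) in the 4 libraries, with colour for the fraction, marker shape for the pool and a short line for the mean of each fraction. Iqgap3 stands near 0 in 3 libraries and at 9.32 CPM in IQ3pos_1910A, and the IQ3pos libraries lie above the IQ3neg libraries for Gkn1, Tff1, Tff2 and Atp4b and below them for Psca, Clps, Sst and Chga.

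Cell division genes stood far higher in IQ3pos. Of the 64 tested genes of G2 phase and mitosis, 59 were higher in both IQ3pos libraries, and 55 rose and 0 fell when adjusted over the list alone, against 0 over all genes tested. Their median log2 difference was 3.55, or 2.87 above that of all genes. Top2a, a DNA topoisomerase of dividing cells, stood at 525 ± 237 CPM against 40.4 ± 16.9, and Hmgb2, a chromatin protein, at 396 ± 159 against 31.2 ± 6.84. Smc4, a condensin subunit, stood at 216 ± 0.795 against 19.2 ± 6.79. Of 55 genes of S phase and DNA replication, 24 rose and 0 fell over the list alone, with a median 1.55 above all genes. Among them were Tyms (264 ± 104 against 47.0 ± 0.373 CPM) and Rrm1 (231 ± 85.8 against 33.5 ± 10.5), which supply nucleotides. Both lists passed camera (adjusted p = 1.49e-17 and 5.83e-08), and neither did at adjusted p = 0.653 with an estimated correlation. The counts over the list alone moved with each library left out: that of S phase became 0 without any one of the 4, and that of G2 and mitosis 21, 0, 0 and 29 without IQ3pos_1909A, IQ3pos_1910A, IQ3neg_1909B and IQ3neg_1910B. With the shift taken out, S phase counted 11, 12, 0 and 8, and G2 and mitosis 46, 49, 39 and 45. Without IQ3pos_1909A, IQ3pos_1910A, IQ3neg_1909B and IQ3neg_1910B, the S phase median above all genes was 2.21, 1.23, 1.44 and 1.61. In the same order, that of G2 and mitosis was 3.37, 2.56, 2.29 and 3.47. Only 9 of 69 listed replication-dependent histone genes reached the filter, at a median of 3.46 CPM in IQ3pos and 1.49 in IQ3neg. These 9 did not pass camera (adjusted p = 0.685). In edgeR with TMM, 29 were tested, with a median 0.96 above all genes (camera adjusted p = 0.301). The histone result thus depended on the filter, and with 9 of 69 genes tested it is weak evidence on cell division either way. Hist1h2bc stood at 73.8 ± 19.9 CPM in IQ3pos and 90.7 ± 17.5 in IQ3neg, and Hist1h1c at 22.0 ± 1.47 and 15.9 ± 10.5, and 0 of the 9 passed over the list alone.

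Markers of surface pit cells, which line the stomach with mucus, were higher in IQ3pos as a group. Of 10 tested, 6 rose and 1 fell when adjusted over the list alone, and the median was 2.06 above all genes. Those that rose were Gkn1, Gkn2, Tff1, Muc5ac, Sult1c2 and Mucl3. Muc5ac, the main surface mucin, stood at 575 ± 156 CPM against 70.7 ± 44.9. Psca, a surface antigen, was the member that fell, at 2419 ± 84.7 against 7707 ± 847 CPM. It was lower under all 23 settings that tested it. Over all genes its adjusted p was 0.0294 in limma on TMM-scaled CPM and 0.00210 in edgeR with TMM. The list passed camera (adjusted p = 0.00114), but not with an estimated correlation (adjusted p = 0.653 with an estimated correlation) and not without IQ3pos_1910A (adjusted p = 0.0821). Psca did not pass over the list alone without any one of the 4 libraries.

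Markers of acid-secreting parietal cells moved the same way. Of 17 tested, 10 rose and 1 fell over the list alone, with a median 1.55 above all genes. Atp4b stood at 2636 ± 635 CPM against 304 ± 6.08, Car2, a carbonic anhydrase, at 3846 ± 481 against 582 ± 365, and Atp4a, the pump's catalytic subunit, at 795 ± 80.4 against 156 ± 55.9. Cckbr, the gastrin receptor gene, fell, at 5.26 ± 1.17 against 63.9 ± 44.5 CPM. The list passed camera (adjusted p = 0.00149), but not with an estimated correlation (adjusted p = 0.653 with an estimated correlation) and not without IQ3pos_1909A (adjusted p = 0.159). The 10 risen genes became 3, 5, 6 and 9 without IQ3pos_1909A, IQ3pos_1910A, IQ3neg_1909B and IQ3neg_1910B, and the fall of Cckbr was lost in each case. With the shift taken out the risen genes were 7, 8, 5 and 6, and 1 member fell under each of these settings.

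Mucous neck cell markers were split. Tff2 stood at 4864 ± 888 CPM in IQ3pos against 505 ± 128 and rose over the list alone (not without IQ3neg_1909B), while Muc6, the gland mucin, stood at 394 ± 19.0 against 410 ± 207 and Gkn3 at 1652 ± 1547 against 760 ± 363. The list of 4 did not pass camera (adjusted p = 0.299). Of 5 markers of spasmolytic polypeptide-expressing metaplasia, a gland state seen after injury, Gpx2 and Dmbt1 rose over the list alone and camera gave an adjusted p of 0.0597. The list passed camera without IQ3pos_1909A (adjusted p = 0.0392), and without any one of the other libraries 0 members passed over the list alone. With the shift taken out the 2 became 0, 2, 0 and 0, and the camera adjusted p was 0.0486, 0.0429, 0.0618 and 0.0726. Gpx2 stood at 210 ± 77.2 against 46.2 ± 30.6 CPM and Clu at 2700 ± 738 against 1615 ± 436. Isthmus progenitor markers did not pass as a group (11 tested, 0 over the list alone, adjusted p = 0.656). Their most abundant members, Sox9 and Prom1, stood at 487 ± 66.7 against 269 ± 141 CPM and at 386 ± 199 against 256 ± 110. Stmn1, chosen after its value was seen, stood at 186 ± 109 against 20.5 ± 15.1 CPM.

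Chief cell markers, genes of the zymogen-secreting cells at the gland base, were lower in IQ3pos. Of 11 tested, 0 rose and 6 fell when adjusted over the list alone, and the median lay 2.91 below all genes. Clps stood at 19430 ± 17376 CPM in IQ3pos and 309031 ± 45204 in IQ3neg, and Pgc at 10810 ± 1409 and 52873 ± 21710. The others that fell were Cblif (intrinsic factor), Chia1, Pnliprp1 and Pnliprp2. Pga5, Rab3d, Xbp1 and Lgr5 did not pass, and Pga5, a pepsinogen gene, stood at 132 ± 31.6 against 105 ± 85.8 CPM. The list passed camera (adjusted p = 9.48e-08), though not with an estimated correlation (adjusted p = 0.653 with an estimated correlation). The 6 fallen genes became 1 without either IQ3pos library and 0 without either IQ3neg library. With the shift taken out they were 8, 8, 5 and 8, and without the 20 most abundant genes the median was −1.22 relative to all genes.

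Enteroendocrine genes showed the deepest deficit among the lists of stomach cell types. Of 17 tested, 10 fell and 0 rose over the list alone, and 11, 11, 10 and 12 fell with the shift taken out. The median relative to all genes was −3.73, or −4.76, −4.52, −4.41 and −4.03 without IQ3pos_1909A, IQ3pos_1910A, IQ3neg_1909B and IQ3neg_1910B, and −5.81 in edgeR with TMM. Besides Chga, Sst and Hdc, the genes that fell included Ghrl, encoding ghrelin, at 88.1 ± 70.5 CPM in IQ3pos against 3227 ± 1319. The list passed camera (adjusted p = 1.01e-14), with adjusted p = 0.537 with an estimated correlation. Markers of tuft cells, a chemosensory type, also passed camera (10 tested, 0 over the list alone and 2, 2, 1 and 1 fallen with the shift taken out, median 2.27 below all genes, adjusted p = 6.70e-05), with adjusted p = 0.653 with an estimated correlation. Rgs13 stood at 241 ± 195 against 430 ± 271 CPM and Dclk1 at 44.4 ± 49.5 against 134 ± 116. The tuft difference was found mainly among the 4-mouse pools: the list's median log2 difference was −0.10 among the 3-mouse pools and −3.58 among the 4-mouse pools, a contrast that was not tested, and its median relative to all genes was −2.88, −1.32, −3.08 and −1.17 without IQ3pos_1909A, IQ3pos_1910A, IQ3neg_1909B and IQ3neg_1910B.

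Genes of protein synthesis and respiration were higher in IQ3pos in CPM, and their medians lay above that of all genes. Of 82 cytosolic ribosomal protein genes, 72 passed as higher and 0 as lower over the list alone, and 17, 1, 0 and 0 as higher with the shift taken out, with a median 1.07 above all genes. Rpl4 stood at 1095 ± 12.6 CPM against 320 ± 14.3 and Rps3 at 752 ± 56.1 against 213 ± 36.7. Of 72 nuclear genes of oxidative phosphorylation, 64 passed as higher and 0 as lower, and 0 under each of the 4 settings with the shift taken out, with a median 0.89 above all genes. Uqcrc1, of respiratory complex III, stood at 1882 ± 147 against 505 ± 171 CPM and Atp5g1, of the ATP synthase, at 1008 ± 57.2 against 304 ± 19.9. Of 24 ribosome biogenesis genes, 7 passed as higher and 0 as lower, and 0 under each of those 4 settings, with a median 0.91 above all genes, among them Npm1 (265 ± 52.5 against 54.8 ± 7.84 CPM) and Ncl (364 ± 42.3 against 106 ± 28.3). All 3 lists passed camera (adjusted p = 5.28e-23, 2.51e-21 and 0.000470), with adjusted p = 0.384, 0.653 and 0.653 with an estimated correlation. The count for oxidative phosphorylation became 0 without IQ3pos_1909A and 41 without IQ3neg_1910B, and that for ribosome biogenesis 0 without any one of the 4 libraries. The 12 mitochondrially encoded transcripts did not pass (0 over the list alone, adjusted p = 0.374), though they passed without IQ3neg_1909B (adjusted p = 0.0182, median 1.12 above all genes), with mt-Cytb at 77014 ± 16923 against 38372 ± 24172 CPM and mt-Co1 at 10137 ± 3785 against 7101 ± 5276.

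**Figure D3:**
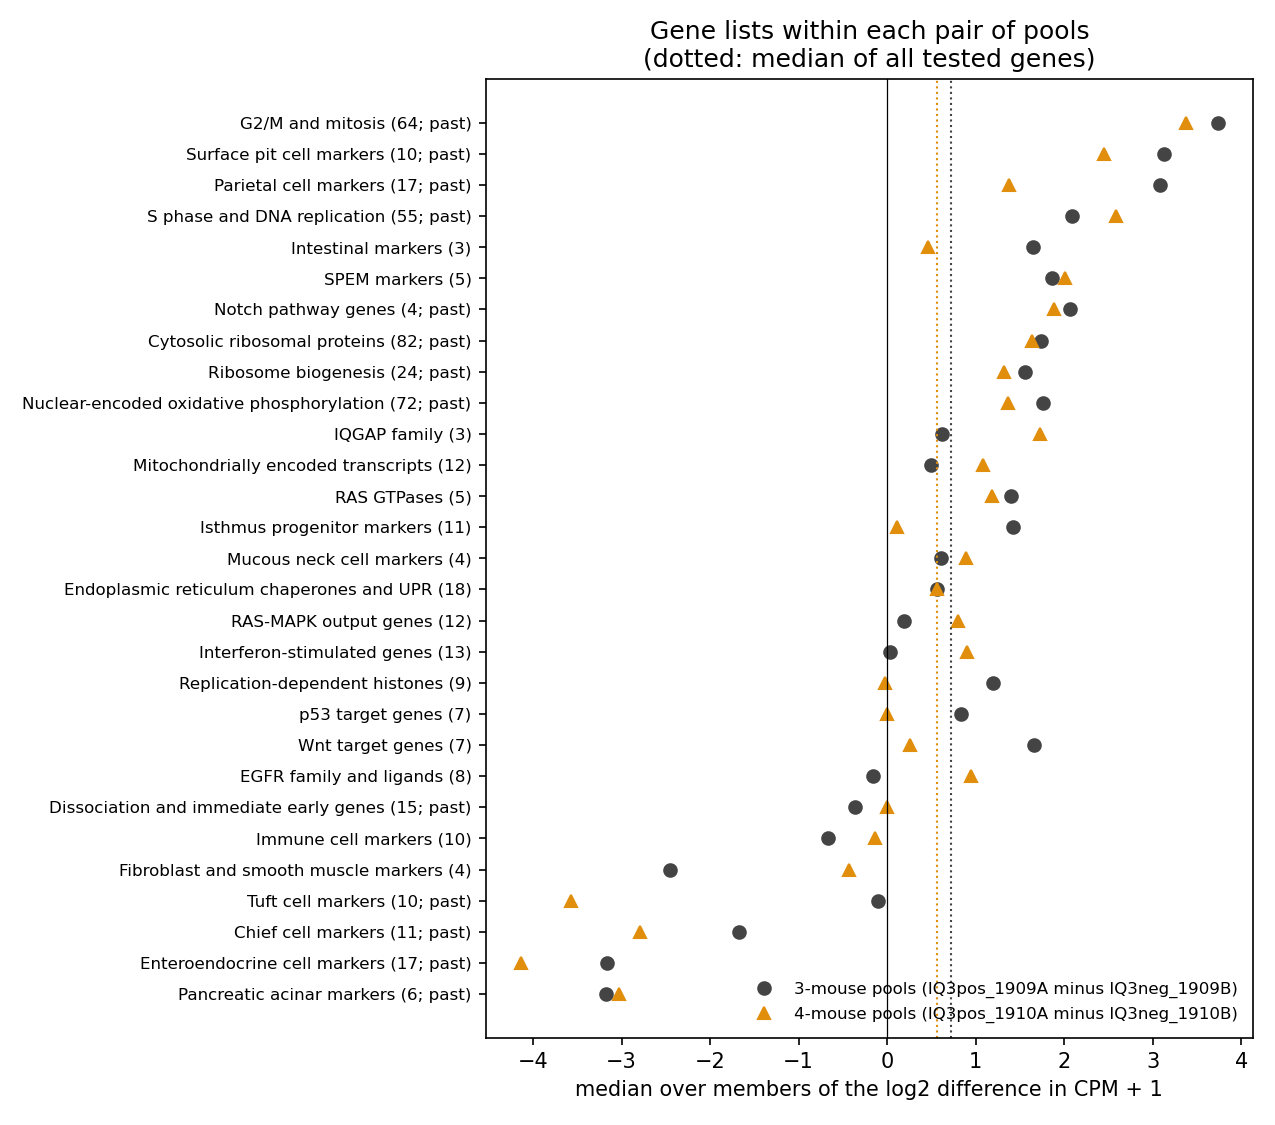
Median over the tested members of each gene list (y axis, members in parentheses, "past" where camera passed) of the log2 difference in CPM + 1 between IQ3pos and IQ3neg (x axis), among the 3-mouse pools and among the 4-mouse pools, with dotted lines at the median of all tested genes. G2 and mitosis genes lie at 3.73 and 3.37, whereas tuft cell markers lie at −0.10 in the 3-mouse pools and −3.58 in the 4-mouse pools.

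The series title names a RAS axis, and as lists neither the RNA of the RAS genes nor that of their output genes stood apart. RNA levels were compared here, and RAS activity was not measured. Of 5 RAS GTPase genes, Nras rose over the list alone (433 ± 66.9 against 174 ± 54.9 CPM), though not without any one of the 4 libraries nor with the shift taken out, and the list gave a camera adjusted p of 0.547. The 12 tested output genes of RAS and MAPK signalling lay 0.05 below all genes in the median (0 over the list alone, camera adjusted p = 0.990). In edgeR with TMM, 13 were tested and their median lay 0.65 above all genes (camera adjusted p = 0.864). Spry2 stood at 472 ± 318 against 269 ± 93.1 CPM and Egr1 at 170 ± 46.5 against 201 ± 6.35. The 8 genes of the EGFR family and its ligands gave 0 over the list alone and an adjusted p of 0.685, with Erbb3 at 51.0 ± 4.62 against 13.3 ± 2.99 CPM and Btc at 52.1 ± 32.6 against 12.2 ± 5.26. Wnt targets (7 tested, 0 over the list alone, adjusted p = 0.912) did not pass either, with Znrf3 at 287 ± 18.1 against 214 ± 9.12 CPM. Of 4 Notch pathway genes, Jag1, Notch2 and Hes1 passed as higher over the list alone, and 0 did with the shift taken out, without IQ3pos_1909A or without IQ3neg_1910B. Jag1 stood at 134 ± 51.5 against 26.8 ± 2.55 CPM and Notch2 at 381 ± 88.6 against 115 ± 39.8. The Notch list passed camera at adjusted p = 0.0459, with adjusted p = 0.653 with an estimated correlation, and did not pass without any one of the 4 libraries, with adjusted p from 0.0518 to 0.313. With the shift taken out it was 0.0484, 0.0566, 0.0418 and 0.650.

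Among stress and response lists, 1 of 4 passed. Immediate early genes, which dissociation can induce, passed camera as lower in IQ3pos (15 tested, 0 over the list alone, median 0.84 below all genes, adjusted p = 0.0459), with adjusted p = 0.653 with an estimated correlation. This call was lost without any one of the 4 libraries (adjusted p from 0.0822 to 0.188). With the shift taken out, 3, 3, 6 and 2 members fell over the list alone and the camera adjusted p was 1.29e-04, 1.94e-04, 3.36e-05 and 0.00167. Fos stood at 505 ± 33.8 against 456 ± 33.8 CPM, a log2 difference of 0.15 that turned to −0.62 with TMM-scaled CPM, and Btg2 stood at 247 ± 19.0 against 487 ± 127. Endoplasmic reticulum chaperones (18 tested, 2 higher over the list alone, adjusted p = 0.408), interferon-stimulated genes (13 tested, 0, adjusted p = 0.685) and p53 targets (7 tested, 0, adjusted p = 0.685) did not pass. Pdia3 and Manf, both of protein folding, were the chaperone genes higher over the list alone (2262 ± 336 against 903 ± 168 CPM and 481 ± 36.3 against 198 ± 16.8), and both calls were lost without any one of the 4 libraries. The direction turned with the shift taken out, to 0 chaperone genes higher and 3, 2, 4 and 3 lower. Bst2 stood at 43.3 ± 30.5 against 12.6 ± 3.55 CPM, Oasl2 at 35.4 ± 47.4 against 13.2 ± 7.24, Perp at 122 ± 8.97 against 48.4 ± 14.6 and Ccng1 at 93.6 ± 8.26 against 51.8 ± 3.96. In the isthmus, mucous neck, RAS output, Wnt and chaperone lists the median lay below that of all genes while the mean and camera's direction lay above, and in the interferon list the mean alone lay above.

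Digestive enzyme genes that the pancreas also makes were higher in IQ3neg. Of 11 pancreatic acinar genes, 6 were tested, 3 fell over the list alone and 0 rose, 4 fell under each of the 4 settings with the shift taken out, and the list passed camera as lower in IQ3pos (adjusted p = 0.000265), with adjusted p = 0.537 with an estimated correlation. Cel, a lipase gene, stood at 7.86 ± 10.6 CPM against 622 ± 58.4, and Try4 at 15.0 ± 8.85 against 325 ± 33.7, and Cela2a was the other that fell. Cela1, an elastase gene, stood the other way, at 125 ± 81.4 against 22.4 ± 27.8 CPM. Immune markers (10 tested, 0 over the list alone, adjusted p = 0.0659) did not pass, with Cd74 at 544 ± 497 against 803 ± 785 CPM and Lyz2 at 128 ± 118 against 175 ± 173, and they passed without IQ3pos_1909A (adjusted p = 0.0307) and without IQ3neg_1910B (adjusted p = 0.00384). Fibroblast and smooth muscle markers (4 tested, 0 over the list alone, adjusted p = 0.0580) passed without IQ3neg_1910B (adjusted p = 0.00265), and their most abundant members, Dcn and Vim, stood at 7.72 ± 9.37 and 3.01 ± 2.43 CPM in IQ3neg. Intestinal markers (3 tested, 0 over the list alone, adjusted p = 0.420) did not pass, with Lgals4 at 59.6 ± 12.6 against 32.9 ± 23.5 CPM and Vil1 at 26.9 ± 11.8 against 14.2 ± 19.9. Squamous forestomach markers reached the filter with 0 genes, endothelial markers with 1 (Tek) and erythroid markers with 2 (Hba-a1 and Hba-a2), too few for the list test.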

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

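Alternatives that rescale the CPM, that run edgeR with TMM on the recovered reads or that block in limma were chosen after seeing the data. The main counts of 0 higher and 0 lower genes (limma, 2373 and 648 at unadjusted p under 0.05) stayed at 0 with a pseudocount of 0.1, with no filter, at an adjusted p of 0.01, and from 0 to 0 with each library left out, where a lone library is assumed to vary like the other group. Higher and lower calls were 239 and 54 with a pseudocount of 5, 6 and 24 with TMM-scaled CPM, 16 and 33 with DESeq2-scaled CPM, and 2 and 9 with CPM without the 20 most abundant genes. On recovered reads edgeR called 11 and 38 with TMM, 14 and 39 with DESeq2 size factors, 23 and 67 with upper quartile factors, 82 and 31 with library size only, 16 and 34 without the 20 most abundant genes, 3 and 18 with no filter, 35 and 78 at a CPM of at least 5 in 2 libraries, and 4 and 23 against a 2-fold change. The older quasi-likelihood form called 0 and 8, the likelihood ratio test 297 and 915, limma-voom 6 and 3, and the DESeq2 Wald test 427 and 1705. The cause of these differences was not tested. The labels do not say that same-numbered fractions came from the same mice, so libraries were treated as sharing only a number. A shared pool stays open: mouse numbers are equal within a number, and Ddx3y and Xist go with the number. So do Uty, at 57.9 and 49.0 CPM in IQ3pos_1909A and IQ3neg_1909B, and Eif2s3y, at 24.4 and 14.5 CPM. Both were at or near 0 CPM in the 4-mouse pools. Y-linked Kdm5d differed, at 0.154 CPM in IQ3pos_1909A and 23.3 CPM in IQ3neg_1909B, and this single gene does not decide the question. With 2 numbers, the deviations of same-numbered libraries correlated at 0.148 across genes. The replicate block gave 1216 and 125 calls in limma and 0 and 0 in edgeR. With the block, 3 more lists passed camera in limma: metaplasia (adjusted p = 0.0142, and 0.0395 in edgeR), immune (0.0141, and 0.0706 in edgeR) and mitochondrially encoded (0.0103, and 0.780 in edgeR). The Notch list still passed with the block in limma and did not in edgeR (0.679), where it had not passed without the block either (0.650).

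The 13 of 29 gene lists past camera were 10 to 13 with each library left out and 11 to 16 under the other settings, but 0 with an estimated correlation and 1 with fry. With an estimated correlation camera rests on 2 degrees of freedom, so that 0 decides little. The correlation across genes of the log2 ratios among the 3-mouse pools and among the 4-mouse pools was 0.389, and 0.466 at a CPM of at least 5 in 2 libraries, 0.365 with 0.5 and 0.489 with 5 added to the CPM. Endoplasmic reticulum chaperones turned lower without the 20 most abundant genes (−0.17 relative to all genes, adjusted p = 0.0379). Fos turned from 0.15 to −0.62 with TMM-scaled CPM and −0.84 without the 20 most abundant genes in limma, and in edgeR to −0.67 with TMM, −0.65 with DESeq2 size factors, −0.69 with upper quartile factors, −0.62 without the 20 most abundant genes, −0.76 at a CPM of at least 5 in 2 libraries, −0.67 in the older form and −0.67 with the replicate block, and to −0.70 with limma-voom. These are scalings that take out the general shift of 0.68. Of 1804 other comparisons of a named gene with its main value, 136 differed in sign, as did 82 of 636 for lists. Depth limits the lowest levels, such as Iqgap3 at 5 reads in IQ3neg_1909B, and what limits the number of calls was not tested.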

Other observations

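Some genes differed between the pools and others between the fractions. Ddx3y, a Y-linked gene, stood at 110 and 102 CPM in IQ3pos_1909A and IQ3neg_1909B and at 0 reads in both 4-mouse pools, whereas Xist, which is made from the inactive X chromosome, stood at 0.0992 and 0.0174 CPM in the 3-mouse pools and at 63.9 and 42.4 CPM in IQ3pos_1910A and IQ3neg_1910B. As far as these genes show, the 3-mouse pools were male and the 4-mouse pools female. Each fraction thus had 1 library of each sex, and no contrast between the pools can be told apart from sex. Gast, encoding gastrin, was at 0 reads in both 3-mouse pools and at 19.6 and 487 CPM in IQ3pos_1910A and IQ3neg_1910B. Gcg, encoding glucagon, stood at 176 and 191 CPM in IQ3neg_1909B and IQ3neg_1910B and at 0.0441 and 0.0717 CPM in IQ3pos. Kcnj16, a potassium channel gene, was at 94.8 and 51.3 CPM in IQ3pos_1909A and IQ3pos_1910A and at 0.0348 and 0.00956 CPM in IQ3neg.

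Chief cell genes did not keep the same share of their IQ3neg level in IQ3pos. Among the 3-mouse pools, IQ3pos held 9.30% of the IQ3neg level of Clps, 20.4% of Cblif and 31.5% of Pgc, and among the 4-mouse pools 2.58%, 5.52% and 14.4%. The endocrine gene Sst stood at 1.38% and 1.39%, and Chga at 3.06% and 2.05%. All genes in these 2 paragraphs were chosen after their values were seen.

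In the paragraphs that follow, the tests of a label swap, of the scaling, of a lower chief cell share and of other splits were chosen after the result was seen, and the acinar and drop-out tests were written before. Intervals of medians there run over genes, which share the same 4 libraries and are not independent. They cover no spread between libraries or mice.

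Clps, Pla2g1b and Cel, which the pancreas also secretes, were far higher in IQ3neg. Pancreatic acinar cells in the sort were a candidate source, and EpCAM sorting would not be sure to remove them. If so, other acinar transcripts would come near the level of Clps. The median of the 11 acinar genes was 0.000946% of Clps in the higher of the IQ3neg libraries, and the most abundant, Cel and Try4, reached 0.239% and 0.109% in IQ3neg_1910B, which argues against acinar cells. Expression by IQ3neg stomach cells stays open as a hypothesis and was not tested further.

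Iqgap3 was near the floor in IQ3pos_1909A, a library sorted for its reporter. Exchanged labels between the 3-mouse libraries are argued against, since the G2 and mitosis genes had a median log2 ratio of 3.73 there (95% interval over members 3.33 to 4.54), with 60 of 64 above 0. Loss of transcripts in that library may account for it: of 3193 genes at 5 to 20 CPM in IQ3pos_1910A, 30.5% lay below 0.5 CPM in IQ3pos_1909A. The same share was 11.1% between the IQ3neg libraries, and 21.9% and 4.87% in the reverse direction. A true difference between the pools of mice, which also differed in sex-linked genes, was not tested and stays open.

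Pit and parietal markers were higher in IQ3pos, along with the cell division genes. The share of IQ3neg reads taken by a few genes is argued against as the whole cause, since the 27 pit and parietal genes kept a median of 1.59 (1.24 to 2.22) after TMM scaling. A lower share of chief cells that raises the other types alike is argued against too, for enteroendocrine and tuft genes. Those 27 genes had a median of −2.42 (−4.13 to −1.29), against 2.31 (2.00 to 2.92) for pit and parietal genes. Mucous neck genes were also named in the prediction but left out of this comparison. Their list median was 0.65, with Tff2 at 3.28. Among the 3-mouse pools the list medians were 3.13 for pit, 3.08 for parietal, −3.16 for enteroendocrine and −0.10 for tuft genes. Among the 4-mouse pools they were 2.45, 1.38, −4.14 and −3.58. More pit and parietal cells carried along in that sort, and such transcripts in the reporter-bright cells themselves, both stay open, and no test here tells them apart.

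Of the 3 splits of the 4 libraries into pairs, 1, the real one, gave as many as 3021 genes at an unadjusted p under 0.05 in limma. The highest of the others, 3-mouse against 4-mouse pools, gave 360. These counts are on CPM, which carry the shift between the fractions. With TMM-scaled CPM the real split gave 994 higher and 1083 lower genes, and the other splits are given for CPM only. After adjustment the split by pool called 1 gene and the real one 0. With 3 splits no share under 0.05 can be reached.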
